A study of Mus musculus with 8 samples.

How the data were processed

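Whole hearts of mouse embryos at E12.5 were compared between 4 WT and 4 Slc39a8 KO samples, named by group and replicate as in the labels, whose numbers call them biological replicates. Per the labels' protocols, hearts were dissected, rinsed and frozen, RNA was extracted with a column kit, and biotinylated cDNA was prepared from 250 ng of total RNA with the Ambion WT Expression protocol for Affymetrix arrays. Per the submitters' processing notes, RMA and Partek 6.6 were used, with no roles stated. RMA corrects background, normalizes quantiles between arrays and summarises probes, so a log2 difference is relative to the array-wide distribution, and a change shared by most transcripts would be removed. The deposited annotation cites transcript coordinates of a genome build older than GRCm38.p6 for many probe sets, but the sources used here do not state the build of the probes. Gene names are those of the deposited annotation, and no coordinates are printed from it.

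The authors deposited a table of RMA log2 values for 34365 probe sets on 8 arrays, and a workbook with the same log2 values (largest difference 0), the means per genotype, the KO to WT ratio, a signed fold change, a p-value with its step-up adjusted value, and a score with a q-value in percent. Per the file headers these statistics compare KO with WT; the score d and the q-value are named as in significance analysis of microarrays. The deposited p-value, ratio, fold change, score and q-value were used only to quote the authors' deposited table. No column of per-sample values was left unmatched.

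Of the probe sets, 27037 carry a gene symbol in the deposited annotation and 7328 do not. Where a symbol had several probe sets, the one with the highest mean log2 over all 8 arrays was kept, which left 24647 genes. The annotation text names more than 1 symbol for 1661 probe sets, and 16675 of its cells end at 255 characters, so further symbols may be missing there. The RefSeq gene table of GRCm38.p6 was used only for names, and 21227 of the file's symbols are current symbols in it. No filter on dim probe sets was applied.

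Differences were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only factor, all 8 arrays, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The residual SD had a median of 0.0980 over genes. Single genes were also given an exact two-sided permutation test over the 70 assignments of 4 of 8 arrays. Before the data were examined, 33 gene lists with 600 entries were fixed, together with the tests, the alternatives and the rule for naming genes. Of the entries, 595 were measured, 7 of them under an older symbol. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with limma's fry. A mean per list is the mean log2 difference of its members. Tests over annotation terms were planned only for an annotation that carries terms, and were not run.

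The genes named are Slc39a8; in each direction the 12 largest differences past the threshold without overlap between genotypes; where under 5 pass in a direction, the 5 smallest unadjusted p in that direction, given as not passing, leaving out predicted and non-coding models; and up to 4 members with the smallest unadjusted p of each list. Genes named outside this rule are said to be so, and 4 genes that the rule selects are not reported here.

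The alternatives were the workbook's values, arrays centred on their medians, quantile normalization repeated, the dimmest 30% of genes left out, the mean of a gene's probe sets, every probe set tested, eBayes with trend and robust set, array weights, unmoderated variance, the replicate number as a block, each array left out in turn, the mean of 4 Y-linked genes or of the erythroid list as a covariate, fry, the estimated correlation, and lists without shared genes. Chosen after the data were seen were probe sets naming 1 symbol, an exact permutation test of list means, leaving out KO replicate 3 together with the Y-linked covariate, and leaving out chromosomes X and Y.

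The gene test was tested on simulated data with the real genes' means and variances drawn from limma's fitted prior, for KO against WT with 24647 genes. The simulated genes were independent, and 200 were changed in each of 5 runs. It called 81.5% of 335 genes changed by 0.5 log2 units, 98.2% of 335 changed by 1 and 100% of 330 changed by 2. Of 122235 unchanged genes, 39 were called. These shares hold for independent genes with that many changed, so they do not give the share that would be called in the real data. The list test called 60 of 60 lists shifted by 0.2 and 2 of 600 unshifted lists; that simulation has independent genes, so it says nothing of lists whose genes vary together. Figures were drawn with matplotlib.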

Results

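Gene expression was profiled in whole hearts of mouse embryos at E12.5, a stage counted in embryonic days, when the ventricular wall is forming its inner trabecular and outer compact layers and the valves are growing from the endocardial cushions. The labels give 4 wild-type (WT) and 4 Slc39a8 knockout (KO) hearts, described as biological replicates, from matings of heterozygous mice. Biotin-labelled material from 250 ng of total RNA per heart was hybridised to an Affymetrix-type array, which gave 34365 probe sets as log2 values on each of the 8 arrays. The median log2 value per array lay between 6.80 and 6.87, and correlations between arrays lay between 0.988 and 0.998. With 4 arrays per genotype, the number of arrays limits the precision of each value. The comparison asks which transcripts differ in the embryonic heart when Slc39a8 is disrupted.

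Slc39a8 encodes a ZIP-family transporter that carries zinc and other divalent metal ions into cells, and its transcript had the smallest p of all genes tested. Its log2 value was 9.03 ± 0.0799 in WT (SD, n = 4) and 7.86 ± 0.239 in KO (SD, n = 4). The single probe set for the gene (17402936, chromosome 3, band G3) fell by 1.17 on the log2 scale (SE 0.106, limma adjusted p = 0.0168), which is 2.25-fold lower. The WT arrays gave 9.09, 9.08, 8.92 and 9.03, and the KO arrays gave 7.53, 7.91, 8.11 and 7.89 for replicates 1 to 4, so all 4 libraries labelled KO lay below all 4 labelled WT. The exact permutation test of this gene gave p = 0.0286 (two-sided), the lowest value that 4 arrays against 4 can give. Which part of the gene was deleted is not given in the sources used here, and a probe outside a deleted part would not report on it. Leaving out KO replicate 1 gave an adjusted p of 0.00169 and leaving out WT replicate 1 gave 0.150, and 6 of the 8 such settings left Slc39a8 above the threshold of 0.05. In the authors' deposited table the signed fold change was -2.25, with p = 8.96e-05 and a step-up adjusted p of 0.215. No probe set there had a lower step-up value, but Slc39a8 did not have the smallest deposited p, as that of Sorl1 was 5.56e-05. Slc39a8 was among 14 probe sets with a q-value of 0%.

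Beyond the targeted gene, no other transcript passed the limma threshold among the 24647 genes tested: 0 genes were higher and 1 gene was lower in KO at an adjusted p under 0.05. At an unadjusted p under 0.05 limma gave 2965 genes, of which 1550 were higher and 1415 lower in KO, where chance alone would give about 1232 on average. Other splits of the 8 arrays into 4 and 4 gave from 383 to 2764. The 4 KO values did not overlap the 4 WT values in 1876 genes, or 7.61%, where chance gives 2.86%. The count past the threshold depended on single arrays and on their weighting. Without KO replicate 1, limma gave 15 genes higher and 4 lower, and with array weights it gave 3 higher and 8 lower. The authors' deposited table lists 34 probe sets with a q-value under 5%, 18 lower and 16 higher in KO.

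The genes closest to the threshold did not pass it, and they come from several functions. In the upward direction, the smallest p belonged to Sorl1, a sorting receptor, with a log2 difference of 0.49 (SE 0.0563, adjusted p = 0.0675). It was followed by Slc35d3, a nucleotide-sugar transporter family member (0.41), Aldh1a1, a retinaldehyde dehydrogenase (0.73), Mthfd2, a mitochondrial folate enzyme (0.50), and Tnnt3, the fast skeletal troponin T (0.76). In the downward direction, Scube2, a secreted EGF-domain protein, stood first with a log2 difference of -0.51 (SE 0.0622, adjusted p = 0.0675). Slc24a3, a potassium-dependent sodium/calcium exchanger (-0.45), Cdh6, a cadherin (-0.39), and Cntfr, a cytokine receptor (-0.42), were among those that came next. All 9 genes named here separated the 4 KO from the 4 WT arrays without overlap, and their adjusted p lay between 0.0675 and 0.0978. With array weights, Sorl1, Slc35d3, Aldh1a1, Scube2, Slc24a3, Cdh6 and Cntfr were among those that passed, with adjusted p from 0.0369 to 0.0493.

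**Figure D1:**
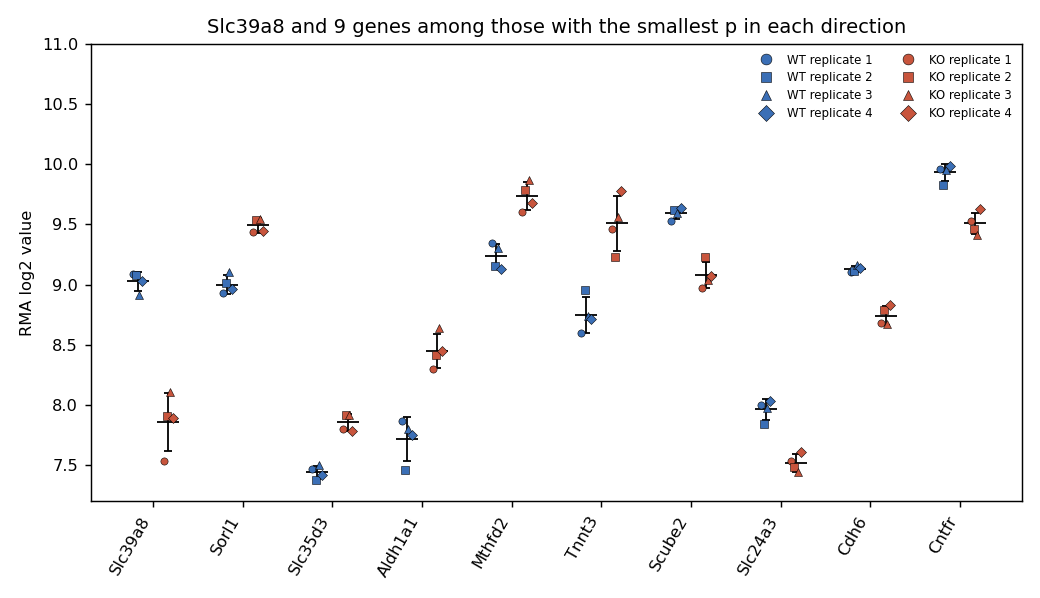
RMA log2 value (vertical axis) of Slc39a8 and of 9 other genes among those with the smallest p in each direction, per array; markers are arrays, horizontal bars are group means and error bars are SD (n = 4). The KO and WT arrays do not overlap for any of the 10 genes, with Slc39a8 means of 9.03 in WT and 7.86 in KO.

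Of the 33 gene lists tested, 9 shifted upward and 6 shifted downward in KO by limma's camera with a preset correlation between genes. No list passed with the correlation estimated from the arrays, where the lowest adjusted p was 0.357. No member of any list passed over all genes. Members said to be higher or lower are counted by the sign of their difference, whatever its p, and the members that passed adjusted over the list alone are counted apart.

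Genes of the hypoxia response and of glycolysis were higher in KO across the list. All 24 measured members had a positive log2 difference, with a mean of 0.36 (adjusted p = 5.6e-12, and adjusted p = 0.396 with an estimated correlation). Of these, 15 reached an unadjusted p under 0.05 and 11 passed adjusted over the list alone. Pfkl, a phosphofructokinase subunit, had a log2 difference of 0.31 (SE 0.0655), Higd1a, a hypoxia-inducible mitochondrial protein, 0.39 (SE 0.110), Ero1l, an oxidase of the endoplasmic reticulum, 0.52 (SE 0.155), and P4ha1, a collagen prolyl hydroxylase subunit, 0.37 (SE 0.112). The list's mean per array was 10.1 ± 0.0610 in WT and 10.5 ± 0.337 in KO (SD, n = 4), and KO replicate 3 stood highest at 10.96. Without KO replicate 3 the difference in the mean was 0.20.

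Among the 15 called lists, red cell genes showed the largest mean difference. All 19 erythroid members were higher in KO, with a mean of 0.83 (adjusted p = 5.2e-10, and adjusted p = 0.427 with an estimated correlation), and 9 passed adjusted over the list alone. Hemgn had a log2 difference of 1.47 (SE 0.312), the erythroid transcription factor Klf1 1.28 (SE 0.280) and Gata1 0.69 (SE 0.185). The 6 globins measured did not shift as a list over all arrays (mean 0.27, adjusted p = 0.235), though they passed without KO replicate 1 (mean 0.48, adjusted p = 0.00484) and without WT replicate 2 (mean 0.40, adjusted p = 0.0339), and their mean was 0.08 without KO replicate 3. With the erythroid mean as a covariate the globins passed as lower (mean -0.32, adjusted p = 3.3e-05). By gene, the embryonic beta-like globin Hbb-bh1 had a log2 difference of 1.05 (SE 0.360), Hba-x 0.29 (SE 0.195), and Hba-a2, which lay near the top of the scale at 13.8 in WT, -0.05 (SE 0.0970). The erythroid mean per array was 8.84 in KO replicate 1, inside the WT range of 8.52 to 9.36, and 9.98, 10.5 and 9.68 in KO replicates 2, 3 and 4. Iron and manganese genes moved with them: 15 of 20 were higher, with a mean of 0.19 (adjusted p = 0.00809, and adjusted p = 0.396 with an estimated correlation), and without KO replicate 2 the adjusted p was 0.0950. The median was 0.07, and the list's difference was -0.003 among the arrays with Y-linked expression and 0.27 among those without. The transferrin receptors Tfrc (0.74, SE 0.186) and Tfr2 (0.59, SE 0.187), the metal exporter Slc30a10 (1.01, SE 0.357) and the iron hormone gene Hamp (0.15, SE 0.0492) had the smallest p, and none passed adjusted over the list alone. Hamp lay low on the scale, at 4.14 in WT and 4.29 in KO, where the lower quartile of every array was at least 5.47. With the erythroid mean as a covariate the iron and manganese mean difference was 0.05 (adjusted p = 0.344).

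**Figure D2:**
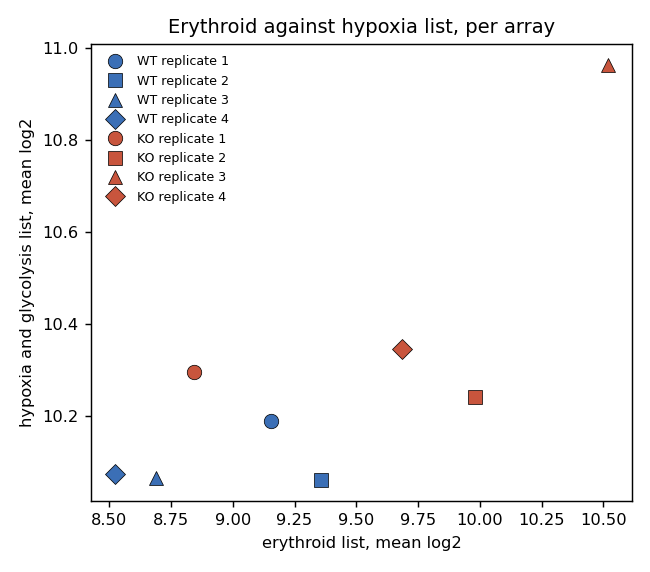
Mean log2 value of the erythroid list (horizontal axis) against that of the hypoxia and glycolysis list (vertical axis), 1 marker per array, with WT in blue and KO in red. KO replicate 1 lies at 8.84 and 10.30, with an erythroid value inside the WT range and a hypoxia value above the highest WT array at 10.19.

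Metabolic and stress lists were also shifted upward. Of 23 cholesterol synthesis genes, 21 were higher in KO, with a mean of 0.20 (adjusted p = 3.8e-08, and adjusted p = 0.357 with an estimated correlation), and 7 passed adjusted over the list alone. Hmgcs1, an early pathway enzyme (0.24), Fdps (0.28) and Sqle (0.29) were among those with the smallest p. Of 23 integrated and endoplasmic reticulum stress genes, 19 were higher, with a mean of 0.24 (adjusted p = 3.2e-07, and adjusted p = 0.357 with an estimated correlation), and 5 passed adjusted over the list alone. Those with the smallest p were the folate and serine pathway genes Mthfd2 (0.50) and Shmt2 (0.41), asparagine synthetase Asns (0.69) and the stress pseudokinase Trib3 (0.69), and without KO replicate 3 the list's mean was 0.16. Of 36 oxidative phosphorylation genes 31 were higher, by a mean of 0.08 (adjusted p = 2.6e-05, and adjusted p = 0.457 with an estimated correlation), 7 of them at an unadjusted p under 0.05 and none passing adjusted over the list alone, with Sdhd (0.22), Cox4i1 (0.24), Ndufa1 (0.31) and Cox5a (0.22) having the smallest p. Of 31 cell cycle genes 25 were higher, by a mean of 0.06 (adjusted p = 0.00375, and adjusted p = 0.521 with an estimated correlation), 5 of them at an unadjusted p under 0.05 and none passing adjusted over the list alone. Aurkb (0.26), Cdt1 (0.25), Cenpa (0.17) and Ccnb1 (0.15) led that list, and its mean was 0.03 without KO replicate 2 (adjusted p = 0.121) and 0.09 without KO replicate 3. Of 17 immediate early and heat shock genes 16 had a positive difference, none of them at an unadjusted p under 0.05, and the list's mean was 0.27 (adjusted p = 0.0114, and adjusted p = 0.459 with an estimated correlation). That shift rested on KO replicate 3, where Fos reached 9.19 and Ier3 12.4, and without this array the mean was 0.06 and the adjusted p 0.264. With the erythroid mean as a covariate the mean was 0.01 and the adjusted p 0.909. Egr1 had a log2 difference of 0.38 over all arrays and 0.10 without KO replicate 3. Jun was the list's only lower member at -0.16, and the only member at an unadjusted p under 0.05.

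Epicardial markers were higher in KO and cushion mesenchyme markers lower. All 13 epicardium genes had positive differences, with a mean of 0.27 (adjusted p = 1.3e-06, and adjusted p = 0.357 with an estimated correlation), and 4 passed adjusted over the list alone. These were Aldh1a1 (0.73, SE 0.0981), mesothelin Msln (0.60, SE 0.142), keratin Krt19 (0.77, SE 0.204) and Gpm6a (0.24, SE 0.0744). Of 12 cushion and valve mesenchyme genes, 11 were lower, with a mean of -0.21 (adjusted p = 1.3e-05, and adjusted p = 0.357 with an estimated correlation), and 7 passed adjusted over the list alone. Among them were the transcription factors Snai2 (-0.32, SE 0.0748), Sox9 (-0.37, SE 0.0904) and Prrx1 (-0.39, SE 0.107) and the growth factor Tgfb2 (-0.26, SE 0.0717). Of 17 cardiac transcription factors, 15 were lower, with a mean of -0.12 (adjusted p = 7.5e-04, and adjusted p = 0.357 with an estimated correlation). Isl1, a marker of second heart field progenitors, had a log2 difference of -0.49 (SE 0.152), Tbx2 -0.20, Tbx3 -0.24 and Myocd -0.17, and none passed adjusted over the list alone. With the erythroid mean as a covariate this list had a mean of -0.05 and an adjusted p of 0.0632.

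Genes of the extracellular matrix and of the ADAMTS, MMP and ADAM families were lower in KO. Of 32 cardiac jelly and proteoglycan matrix genes, 27 were lower, with a mean of -0.19 and a median of -0.09 (adjusted p = 2.3e-05, and adjusted p = 0.357 with an estimated correlation), and 3 passed adjusted over the list alone. Those were Postn, or periostin (-0.30, SE 0.0549), the proteoglycan Lum (-0.51, SE 0.110) and elastin, Eln (-1.26, SE 0.332), and Tnc followed (-0.48, SE 0.140). Fbln5, named outside the rule, is a member too and stood at -1.44. Of 19 ADAMTS metalloproteases, several of which cleave proteoglycans such as versican, 13 were lower, with a mean of -0.13 (adjusted p = 0.00159, and adjusted p = 0.396 with an estimated correlation), and 5 passed adjusted over the list alone. Adamts5 had a log2 difference of -0.48 (SE 0.0842), Adamts19 -0.34 (SE 0.0591), Adamts15 -0.30 (SE 0.0637) and Adamts7 -0.28 (SE 0.0615), each without overlap between the genotypes. Of 28 members of the MMP and ADAM families 20 were lower, with a mean of -0.08 (adjusted p = 0.00101, and adjusted p = 0.357 with an estimated correlation), and this was the only list that limma's fry also called (adjusted p = 0.0381). Adam22 (-0.32) and the gelatinase Mmp2 (-0.19) passed adjusted over the list alone, while Mmp16 (-0.27) and Adam23 (-0.29) did not. Of 24 collagens 17 were lower, with a mean of -0.08 (adjusted p = 0.00517, and adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, 7 collagens passed as lower, among them Col15a1 (-0.35), Col5a1 (-0.23) and Col26a1, listed under its older symbol Emid2 (-0.26), and 3 passed as higher, among them the basement membrane chain Col4a1 (0.20). Without KO replicate 2 the collagen list had an adjusted p of 0.0788.

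**Figure D3:**
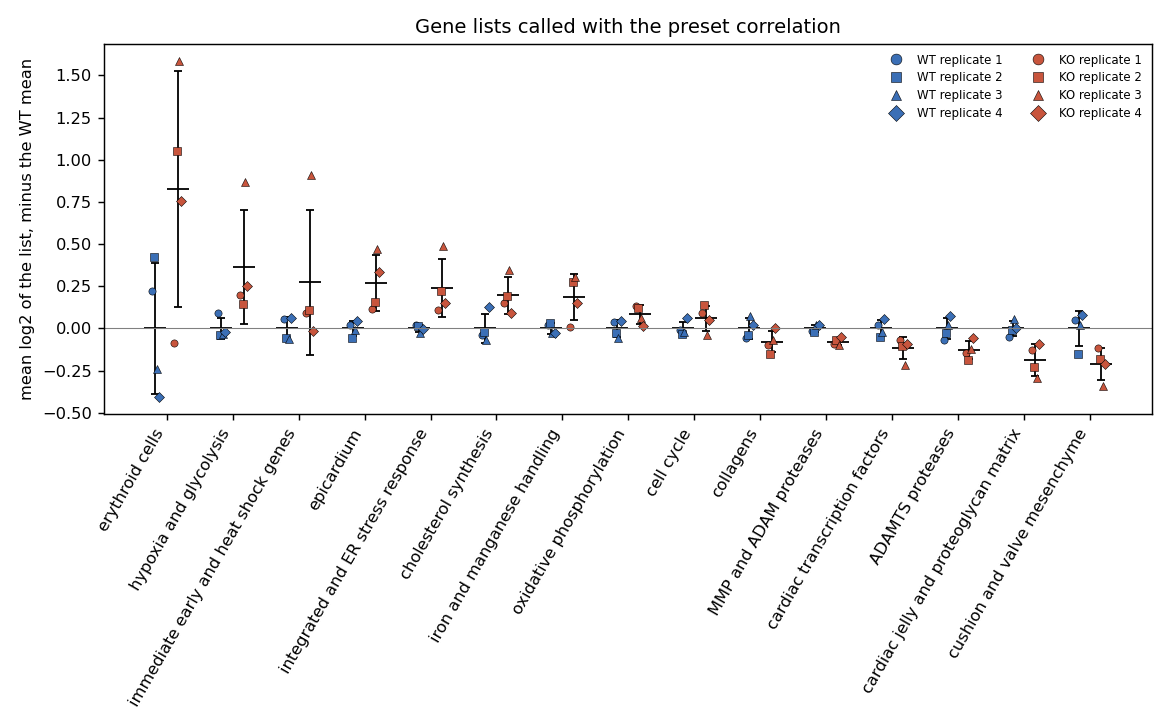
Mean log2 value of each of the 15 called gene lists per array, minus the list's WT mean (vertical axis); markers are arrays, horizontal bars are group means and error bars are SD (n = 4). KO replicate 3 is the highest array for the erythroid list at 10.5 and for the hypoxia and glycolysis list at 10.96, before the WT mean is subtracted.

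The list of zinc-responsive genes did not pass the test over all arrays. The 11 MTF1 target genes, which include the metallothioneins that are induced by zinc, had a mean log2 difference of 0.18 (adjusted p = 0.122), which was 0.06 (adjusted p = 0.311) without KO replicate 3 and 0.23 (adjusted p = 0.0416) without KO replicate 1. It was 0.22 (adjusted p = 0.0472) without genes shared with other lists. Among arrays with Y-linked expression the difference was -0.01, and among those without it 0.33. Mt1 had a log2 difference of 0.56 (SE 0.231, adjusted p = 0.378), or 0.31 without KO replicate 3, Mt3 0.24, Selenoh, listed as 2700094K13Rik, 0.14, and the zinc transporter Slc30a2 -0.13. KO replicate 3 had the highest Mt1 value at 10.8, against 9.53 to 9.93 in the other KO arrays and 9.17 to 9.67 in WT. The 13 other ZIP transporters had a mean of -0.01 (adjusted p = 0.963), with Slc39a6 at -0.15, Slc39a11 at 0.08, Slc39a13 at 0.08 and Slc39a7 at 0.07. The 10 members of the ZnT transporter family had a mean of 0.10 (adjusted p = 0.502), with Slc30a9 at 0.13 and Slc30a8 at 0.09. That mean rested on Slc30a10 (1.01), and it was -0.0024 when only probe sets naming 1 symbol were used, which left this gene out. The 16 chromosomal neighbours of Slc39a8 did not shift (mean 0.01, adjusted p = 0.680), with Emcn at 0.13, Manba at 0.12, Cisd2 at 0.11 and Tacr3 at -0.07.

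Contractile and wall-layer lists did not pass limma's camera. The 28 sarcomere and calcium handling genes had a mean of -0.01 (adjusted p = 0.585), with Myl7 at 0.10, Tcap at -0.18 and Casq2 at 0.11. The 13 trabecular genes had a mean of 0.06 (adjusted p = 0.475) and members in both directions, though the 4 KO arrays, at 10.61 to 10.64, lay above the 4 WT arrays, at 10.55 to 10.59. The exact permutation test of that mean gave p = 0.0286 (adjusted p = 0.118) and fry an adjusted p of 0.0963. Bmp10, a growth factor of trabecular myocardium, had a log2 difference of 0.73 (SE 0.148), Nppb 0.33 (SE 0.108) and Nppa 0.11 (SE 0.0468), while Cpne5 stood at -0.47 (SE 0.0878). Adjusted over the list alone, Bmp10 and Nppb passed as higher and Cpne5 as lower. The 10 compact myocardium genes had a mean of -0.01 (adjusted p = 0.634), with Tbx20 at -0.16, Hopx at 0.14, Prdm16 at -0.15 and Zfpm2 at -0.12. The 27 Notch, neuregulin and BMP genes, which regulate trabeculation, had a mean of -0.0006 (adjusted p = 0.685). Within that list Erbb2 stood at -0.20, Nrg1 at 0.22, Heyl at -0.19 and Jag1 at -0.29.

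Lists for other cell types and stress programmes also stayed above the threshold over all arrays. With each array left out in turn, the macrophage list passed in 4 of the 8 settings, the NRF2 list in 2 and the neuronal list in 1. The macrophage list also passed with the erythroid covariate (mean -0.13, adjusted p = 0.0041), but its mean was -0.04 without KO replicate 2, WT replicate 1 or KO replicate 1 and -0.11 without KO replicate 3, and its difference was -0.17 among arrays with Y-linked expression and 0.05 among those without. The NRF2 list also passed with the Y-linked covariate (adjusted p = 0.0458), but its mean was 0.04 without KO replicate 3. Its difference was 0.0008 among arrays with Y-linked expression and 0.16 among those without. Endothelium and endocardium had a mean of 0.03 (adjusted p = 0.243), with Cldn5 at -0.30, Pecam1 at 0.14 and Esam at 0.10. Macrophage genes had a mean of -0.07 (adjusted p = 0.0709), with Mrc1 at -0.40 as the member that passed adjusted over the list alone, and Lyz2 at -0.26, Cx3cr1 at -0.13 and C1qc at -0.13, or -0.03 without KO replicate 2. Neuronal, neural crest and glial genes had a mean of -0.08 (adjusted p = 0.108), with Prph at -0.22, Fabp7 at -0.39, Stmn2 at -0.34 and Gap43 at 0.12. Foregut and lung epithelium had a mean of 0.07 (adjusted p = 0.285, and p = 0.0286 in the exact permutation test), where Krt18 (0.45) and Etv5 (0.52) passed adjusted over the list alone and Sftpc (-0.12) and Id4 (-0.20) did not. Hepatocyte genes had a mean of -0.03 (adjusted p = 0.502), with Ahsg at 0.26, Apob at -0.16, Trf at 0.21 and Ttr at 0.11. Skeletal muscle progenitor genes had a mean of 0.01 (adjusted p = 0.864), with Myf5 at 0.21, Pax3 at -0.11, Myh8 at -0.08 and Myog at 0.09. NRF2 and antioxidant genes had a mean of 0.07 (adjusted p = 0.108), with Gstm1 (0.42) and Gpx4 (0.18) passing adjusted over the list alone, Gsta4 at 0.24 and Slc7a11 at 0.22. Targets of p53 had a mean of 0.04 (adjusted p = 0.680), with Cdkn1a at 0.33, Sesn1 at -0.14, Plk2 at 0.19 and Bax at 0.11. Mean, median and test differed in sign for 4 of these lists: the chromosomal neighbours (median -0.007, test upward), the Notch list (median 0.02, test downward), skeletal muscle progenitors (median -0.001, test upward) and the ZIP family (median 0.02, test upward with a mean of -0.01).

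The arrays also differed in ways other than genotype. The first principal component held 39.4% of the variance and set the genotypes apart without overlap. On it the WT arrays lay between -12.3 and -7.75, and KO replicates 1, 2 and 4 at -5.73, 7.54 and 4.95. KO replicate 3 lay far out at 31.7. Leaving it out moved the difference of 21 of the 137 genes selected for naming by over 1.5 times, against 1 to 6 for each other array. Beside Mt1 and Egr1, these were, with their values without it, Ier3 (0.29), Fos (0.26), Jun (-0.10), Tfr2 (0.38), Ero1l (0.33), Shmt2 (0.27), Cdkn1a (0.17), Plk2 (0.10), Slc7a11 (0.14), Pecam1 (0.08), Hba-x (0.14), Hba-a2 (-0.12), Beta-s (0.09), Isl1 (-0.32), Tnc (-0.32), Jag1 (-0.17), Myocd (-0.11), Tcap (-0.10) and Id4 (-0.07). Genes of the Y chromosome were expressed in WT replicates 1, 2 and 4 and in KO replicate 1, and Xist in WT replicate 3 and KO replicates 2, 3 and 4. The labels give no sex, and this leaves 3 WT and 1 KO array with Y-linked expression against 1 WT and 3 KO arrays without. The sex-linked list itself had an adjusted p of 0.137, with Ddx3y at -1.86, Uty at -2.44, Kdm5d at -1.94 and Xist at 2.98. Among arrays with Y-linked expression, the KO minus WT difference of the list mean was -0.17 for erythroid genes, 0.19 for hypoxia and glycolysis, 0.11 for epicardium, -0.11 for matrix, -0.14 for ADAMTS and -0.11 for cushion mesenchyme. Among arrays without it, the differences were 1.37, 0.45, 0.33, -0.26, -0.15 and -0.27 in the same order. Slc39a8 differed by -1.53 among the arrays with Y-linked expression and by -0.95 among those without.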

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

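Chosen after results were seen were the linear models of the fixed lists' means, including their use of the planned covariates and of the planned setting without KO replicate 3, the comparisons of globins, the cushion covariate and the counts over splits; the 12 smooth muscle and pericyte genes were tested as chosen before their result was seen. Within each genotype, a value was singled out when the highest or lowest of the 4 arrays stood apart from its nearest neighbour by most of the group's range. This held for 44 of the 342 groups examined, where chance alone singles out about 1 in 20, or 17.1 groups, and 15 of the 44 were in KO replicate 3.

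KO replicate 3 stood apart from the other KO arrays in the mean of the hypoxia and glycolysis list (10.96, others 10.24 to 10.35), of the immediate early and heat shock list (9.41) and of the MTF1 list (9.11). It was the highest KO array for Bmp10 (12.57), Nppb (12.998), Higd1a (9.85), Ero1l (12.05), Shmt2 (12.33), Fos (9.19), Ier3 (12.36) and Egr1 (9.28), and the lowest for Tnc (9.52), Jag1 (9.66), Myocd (11.80) and Stmn2 (7.11). The sex-linked genes separated WT replicate 3 and KO replicate 1 from the rest of their groups. In WT replicate 3 these were Ddx3y at 5.88, Uty at 5.08, Kdm5d at 5.06, Xist at 12.32 and the list mean at 6.69. In KO replicate 1 they were Ddx3y at 9.17, Uty at 9.87, Kdm5d at 9.20, Xist at 5.86 and the list mean at 8.83.

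The remaining values that stood apart were spread over arrays. In WT these were replicate 1 for the hypoxia and glycolysis list (10.19) and Ier3 (10.17), replicate 2 for Col4a1 (9.26), Nppa (13.65), Pfkl (11.05) and Beta-s (5.77), replicate 3 for Tcap (8.48), the NRF2 list (9.85), the neuronal list (7.03) and the MTF1 list (8.49), and replicate 4 for Slc39a6 (9.51), Slc39a7 (10.06) and Stmn2 (8.03). In KO these were replicate 1 for Gpx4 (9.18), replicate 2 for Lyz2 (9.30) and C1qc (6.54), and replicate 4 for Adam22 (7.80), Tacr3 (5.46) and the neuronal list (6.99). Outside the genes tested, a probe set with no gene symbol (17550142) differed by -0.52 log2 units, from 7.56 ± 0.0429 in WT to 7.03 ± 0.0815 in KO (SD, n = 4), with a limma adjusted p of 0.0663 over every probe set.

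The hypoxia and glycolysis list was 0.36 higher in KO. Its difference without KO replicate 3 was 0.20 (95% interval 0.0830 to 0.310, exact permutation p = 0.0571). This argues against this array as the only source, though the interval is for a list picked for its rise. More blood in the KO samples could not be separated from genotype: with the erythroid mean in the model the difference was 0.14 (95% interval -0.35 to 0.64). The erythroid mean itself differs between genotypes, and the hypoxia list's mean varied widely among the KO arrays (SD 0.337). Unequal sex of the embryos could not be separated either, with a difference of 0.32 given the Y-linked mean (95% interval -0.23 to 0.87). That value lies near the 0.36 without it, and with this spread among the KO arrays an interval holding 0 decides nothing. An effect of the knockout stays open beside both.

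The ADAMTS, matrix and cushion mesenchyme lists were together lower in KO, with a mean difference of -0.18 (exact permutation p = 0.0286, the lowest possible). They were put together after each had been seen to be lower, so this p is no independent support. Singly, the exact permutation test gave p = 0.0571 for ADAMTS and for cushion mesenchyme, and 0.0286 for matrix. With the Y-linked mean in the model the difference was -0.17 (95% interval -0.30 to -0.04). This argues against unequal sex as the whole cause, though the interval is for lists picked for their fall. Less great vessel wall in the KO dissections stays open: the mean of 12 smooth muscle and pericyte genes differed by -0.032 (95% interval -0.16 to 0.10, exact permutation p = 0.543), but that list left out Rgs5, Eln and Fbln5 because they had been seen to be lower, so it cannot exclude this. A lower share of cushion mesenchyme was not decided: the ADAMTS difference was -0.13 without and -0.12 with the cushion mean in the model (95% interval -0.30 to 0.06), which removed little of it and widened its interval, and the slope on the cushion mean was 0.05 (95% interval -0.62 to 0.71). Lower expression within these cells was not tested and stays open.

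Red cell genes were 0.83 higher in KO by their mean, while the globins were not higher to the same degree. More blood of the same kind stays open: it would raise both equally, and the gap between the erythroid mean and the mean of Hba-x, Hbb-bh1 and Hbb-b1, the 3 globins above the arrays' medians and below a log2 level of 11, was 0.35 larger in KO (95% interval 0.14 to 0.57), but these globins lie on both sides of the erythroid difference (1.05 for Hbb-bh1, 0.29 for Hba-x and 0.08 for Hbb-b1). Less mature red cells in KO stay open: the log2 ratio of the embryonic Hbb-bh1 to the later Hbb-b1 was 0.97 higher, but these genes were picked after their values were seen, so the ratio is no independent support. The embryonic Hbb-y was not higher, at -0.03 (SE 0.128), though it lay at 12.97 in WT, above the level of 11. The SE for Hbb-b1 was 0.464. Unequal sex of the embryos stays open: the erythroid difference given the Y-linked mean was 0.60 (95% interval -0.59 to 1.79). The exact permutation test of the erythroid mean without that covariate gave p = 0.0857, so an interval holding 0 decides nothing here. KO replicate 1, the only KO array with Y-linked expression, had an erythroid mean inside the WT range. WT replicate 3, the only WT array without it, had an erythroid mean of 8.69. That lay below KO replicates 2, 3 and 4, which also lacked it, at 9.98, 10.5 and 9.68. With 1 such array per genotype, neither decides on sex.

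The 35 splits of the 8 arrays into 4 and 4 were compared with the split by genotype. For the count of genes past the adjusted threshold, 2 of the 35 splits gave at least the real count of 1, and the highest other split gave 35 genes. That other split follows Y-linked expression, which points to a structure of the samples other than genotype. The comparison therefore does not decide on chance for that count. For the number of lists called with the preset correlation, 2 of 35 splits gave at least the real 15, and the highest other split gave 17, with a median of 6.5 over the others. The number of list calls therefore does not exclude chance. For the count at an unadjusted p under 0.05, 1 of 35 splits, the real one, gave as many as 2965, and the highest other gave 2764. The real split thus ranked first, which is the lowest share that 35 splits can give. The split with 2764 set WT replicates 1 and 4 and KO replicates 1 and 2 against the rest. Those arrays had the highest values on the second principal component, which held 19.0% of the variance. These counts were compared after results were seen, and the split by genotype is also unequal in Y-linked expression. Chance is therefore not firmly excluded for that count.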

How the results depend on the processing

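Slc39a8 kept its direction under every alternative run, but not its side of the threshold. Its log2 difference was -1.17 with adjusted p = 0.0523 when every probe set was tested, -1.17 with 0.188 when the variance was not moderated, -1.24 with 0.0629 with the Y-linked covariate, and between -1.25 and -1.06 with each array left out (adjusted p from 0.00169 to 0.150). Other settings left it past the threshold, among them the erythroid covariate (-1.41, adjusted p = 0.000264), array weights (-1.26, 0.00409) and repeated quantile normalization (-1.18, 0.0119). The count of lower genes was 0 with every probe set tested, with unmoderated variance and with the Y-linked covariate. It was 3 after repeated quantile normalization, 4 with the erythroid covariate, 8 with array weights, and 0 to 4 with each array left out. The count of higher genes was 1 with arrays centred on their medians, 3 with array weights and 0 to 15 with each array left out. The cause of these changes was not tested. The replicate numbers do not pair the samples: residuals of same-numbered arrays correlated at 0.08, -0.15, -0.02 and -0.22, and no WT array correlated best with the KO array of its own number. With the replicate block the Slc39a8 difference was -1.17 (adjusted p = 0.213) and the count of lower genes 0.

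The lists called upward numbered 0 and downward 0 with the estimated correlation, 0 and 1 with fry, and 0 and 0 with the exact permutation test of list means, in which 8 lists had the lowest possible p of 0.0286. With each array left out they numbered 7 to 11 and 5 to 8. In these settings direction changed for the lists below, none of which was called over all arrays, and for single genes. The Notch mean was 0.0012 with centred arrays, 0.0021 with probe sets averaged, 0.0093 with the Y-linked covariate, 0.0059 with that and without KO replicate 3, 0.028 with the erythroid covariate, and -0.022 to 0.017 with arrays left out. Skeletal muscle progenitors had -0.0026, -0.0056 and -0.011 in the Y-linked, combined and erythroid settings and -0.0047 to 0.023 with arrays left out. The ZIP family had 0.0021 and 0.023 in the combined and erythroid settings and -0.031 to 0.017 with arrays left out, and compact myocardium 0.0064 in the erythroid setting and -0.026 to 0.00043 with arrays left out. Hepatocytes had 0.0055 without dim genes, ZnT transporters -0.0024 with probe sets naming 1 symbol, and globins -0.32 with the erythroid covariate (adjusted p = 3.3e-05, downward), along with Hba-x (-0.20) and Beta-s (-0.15). With the Y-linked covariate, Kdm5d was 0.055 and Xist -0.12, and 0.080 and -0.14 in the combined setting. Hba-a2 ranged from -0.12 to 0.045 with arrays left out. Among arrays with Y-linked expression alone, the called erythroid list differed by -0.17 and the called iron and manganese list by -0.003. The cause was not tested. The files give no detection calls used here, so the lowest values cannot be set against background.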

Other observations

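Apart from the smooth muscle and pericyte list, the genes in this part were chosen after their values were seen, and none passed the limma threshold over all genes. All 3 genes of the Scube family of secreted EGF-domain proteins were lower in KO, with log2 differences of -0.51 (SE 0.0622) for Scube2, -0.44 (SE 0.0834) for Scube1 and -0.31 (SE 0.123) for Scube3, and adjusted p of 0.0675, 0.186 and 0.366. Picked out because their values were low, Rgs5, a pericyte gene, stood at -1.74 (SE 0.596), and the elastic fibre protein Fbln5 at -1.44 (SE 0.460), beside Eln at -1.26. Their KO arrays varied widely, with SDs of 1.503 for Rgs5 and 1.17 for Fbln5 against 0.298 and 0.175 in WT. In the smooth muscle and pericyte list tested above, Ednra stood at -0.24 and Itga8 at -0.28, Ndufa4l2 at 0.40, and 6 of the 12 genes were higher and 6 lower.

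Within the matrix and ADAMTS lists, several abundant members showed little difference. Versican, Vcan, a substrate of ADAMTS proteases, was 12.2 in both genotypes (log2 difference -0.005, SE 0.0575), fibronectin, Fn1, differed by -0.01 (SE 0.0483) and Adamts1 by -0.07 (SE 0.0945). Among the hypoxia genes, Vegfa stood at 0.64 (SE 0.204) and Egln3 at 0.61 (SE 0.271), and among epicardial genes Wt1 at 0.26 (SE 0.0989), while the epicardial transcription factors Tbx18 and Tcf21 stood at 0.03 (SE 0.0637) and 0.01 (SE 0.0728). Reep6 stood at 1.27 (SE 0.199, adjusted p = 0.113). Mt2 differed by 0.32 (SE 0.321), with KO replicate 3 at 10.48 and the other KO arrays between 9.11 and 9.28.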
